A study of Rattus norvegicus with 7 samples.

How the data were processed

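DNA methylation was profiled by bisulfite sequencing in Sprague Dawley rats after local irradiation of 1 organ. Serum was taken as a source of circulating cell-free DNA, and the irradiated organ as a tissue source. The 7 samples were 1 serum and 1 tissue library for each of skin (45 Gy, electron beam), brain (20 Gy, electron beam) and lung (10 Gy, X-ray), and 1 serum library from untreated rats. There was 1 library per group and therefore no replicates. Per the labels' protocols, DNA was bisulfite converted with an unmethylated spike-in, made into libraries with a kit for single-stranded converted DNA and sequenced as paired reads. Per the submitters' processing notes, cutadapt 1.9.3 and Bismark 0.22.3 were used. The tool that called the regions, its thresholds and the genome build are not given in the sources used here.

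The deposited tables held 1 list of called methylated regions per library. Each region came with its length, its number of CpG sites, and its methylation level as a fraction from 0 to 1, the mean over the sites of the region, per the file headers. Fractions are printed here as percent. A second column with a score held the same value in each row checked, with 0 rows that differed. Each region had at least 4 sites and 50 bp, and there were 0 overlapping regions within a list. The table of the control serum held 1 header line and no values, so irradiated and control serum could not be compared. The lists give no read coverage, so depth is unknown, no counting interval can be given and the coverage minimum planned before the data were examined could not be applied. Stretches of low methylation are missing from the lists and cannot be told from stretches without reads. Region starts were counted from 0, as shown by the distances to annotated starts, which fitted that reading in 100% of the regions checked in each list.

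The methylation level of a library was the mean over its regions weighted by sites. Regions of 2 libraries were matched where each covered at least 50% of the other, and a matched region was counted as different at levels 0.3 (30 percentage points) or more apart. Resemblance of sera and tissues was Pearson's r across matched regions for the 3 by 3 pairs. The statistic was the mean r of the pairs from the same irradiation, after removing the mean of each tissue and each serum, with a one-sided exact permutation p over the 6 pairings. The smallest p that this design allows is 0.167. Serum minus tissue was also taken over the 3 pairs from the same irradiation, with a two-sided exact sign-flip permutation p, a test added after the values were seen. Whether serum and tissue came from the same rats is not given in the sources used here. Marker regions lay 0.3 or more below both other tissues, and were chosen on tissue libraries alone. These rules, the gene lists and the rule for named genes were written before the data were examined. The planned matching left too few marker regions with serum values for a statistic, so 1 bp overlap was taken for it after that was seen. The 1 bp overlap had been listed beforehand as another way of matching.

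Promoters were the 1 kb on each side of the start of 1 transcript per gene, from the gene annotation in the deposited tables, with RefSeq mRNA first. In all, 358 gene names found on several chromosomes were left out, which left 21357 protein-coding promoters. The level of a promoter was the overlap-weighted mean level of the regions in it. A second measure, the called share, was the percent of the window inside called methylated regions. It was added after the data were examined, because the lists leave out unmethylated stretches. The same holds for marker promoters (30 points or more of called share below both other tissues) and for stretches of at least 500 bp uncalled in 1 tissue and called in the other 2.

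Named genes came from 2 rules. Within each of 15 lists, up to 4 genes with a region in the promoter of every library were taken by their spread between libraries. For each library against the other 2 of its kind, the 5 protein-coding genes with the largest promoter difference in each direction were taken, among promoters above the median site count in each library compared. Names that are only contig, LOC or RGD numbers were passed over, which removed 1734 promoters from the tissue comparisons and 1486 from the serum comparisons. The rules were applied to levels. Genes found by applying them to the called share are named as such. Each list's median difference was set against 10000 random lists of the same size, matched on mean called share or mean level. The resulting percentile describes these libraries and is not a test of the irradiation. For the called share this made 105 percentiles, of which 10 lay in the outer 5% against 5.25 by chance. For levels it made 91, of which 6 lay there against 4.55 by chance. These percentiles are not independent, since the contrasts share libraries. Many medians of called share tied with those of the random lists. The counts are therefore no test of an excess.

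The matching and the counts were tested on simulated data in which 200 of the 132338 brain tissue regions were changed by known amounts: 100% were recovered at a change of 0.35 and 100% at 0.5, with 0 false calls. The changed list was a copy in which all regions matched, so this checks the code and not the matching of separately called lists. The pairing statistic was tested on sera simulated over 185684 bins of 10 kb. With 2% of the signal from the sera's own organ the matched pairing came first in 20 of 20 draws, and with 0% in 7 of 20. That simulation assumes independent noise between blocks of bins and sera. Each simulated serum was built from the same tissue library that it was compared with, so the simulation may overstate the sensitivity. Alternatives were regions longer than the median, autosomes only, each chromosome left out in turn, other thresholds, 1 bp overlap, fixed 10 kb bins with at least 50% called in each library, other measures of resemblance and other means. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.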

Results

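The libraries profiled cytosine methylation in serum cell-free DNA and in the irradiated organ of rats, to compare the methylation of circulating DNA after irradiation of different organs. Each group had 1 library, so no difference between irradiations or between organs has a replicate check. Each organ had its own dose, and only lung was given X-rays, so organ, dose and beam cannot be told apart. No tissue library came from untreated rats. Serum and tissue can be compared across 3 pairs from the same irradiation. Skin tissue had 170953 called methylated regions over 2297 Mb, brain tissue 132338 over 2331 Mb and lung tissue 145471 over 2328 Mb. Serum had 132171 regions over 1990 Mb after skin irradiation, 123915 over 2051 Mb after brain irradiation and 125273 over 2067 Mb after lung irradiation. The lists held 14.1 to 14.5 sites with data per kb in tissue and 7.10 to 7.77 in serum. The depth behind a level is unknown. Control serum had no values, so whether irradiated serum differed from untreated serum could not be examined.

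Skin tissue had the lowest methylation level of called regions, 74.8%, followed by lung tissue with 76.5% and brain tissue with 79.7%. Serum levels were 78.9% after skin irradiation, 80.3% after brain irradiation and 80.6% after lung irradiation. Serum lay 4.11 points above skin tissue and 4.04 points above lung tissue, in 21 of 21 chromosomes each. It lay 0.604 points above brain tissue, in 19 of 21 chromosomes, a value that depended on the kind of mean (0.233 points weighted by length and 1.93 points unweighted). Over the 3 pairs the mean was 2.92 points (SD 2.01, exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow). The SD of the level over the 20 autosomes, a spread along the genome and not between animals, ran from 0.375 points in serum after skin irradiation to 0.879 points in brain tissue. Exonic regions had higher levels than intronic regions in each of the 6 libraries, for example 76.2% against 72.9% in skin tissue and 82.0% against 79.4% in serum after lung irradiation. On the X chromosome, serum lists covered 54.7 to 63.1 Mb and tissue lists 114 to 118 Mb.

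Between the irradiated tissues, promoters of the skin list had lower levels in skin and promoters of the lung list, of alveolar and airway genes, lower levels in lung. All 8 measured promoters of the skin list had a lower level in skin tissue than the mean of brain and lung, with a median difference of -9.15 points (percentile 0.24 of the random lists, whose median was -3.03 points). Krt14, the keratin of basal keratinocytes, had 46.1% in skin, 80.3% in brain and 73.7% in lung. The desmosomal cadherin gene Dsg1 had 60.9%, 78.3% and 79.2%, and Sfn, the epithelial 14-3-3 protein, 57.5%, 62.0% and 72.4%. All 9 measured promoters of the lung list were lower in lung tissue, with a median of -6.89 points (percentile 0.05, random lists -0.637 points). Other cell types were also lower in lung tissue: 6 of 7 endothelial and fibroblast promoters (median -4.75 points, percentile 2.68) and 8 of 9 leukocyte promoters (percentile 5.98). Napsa, an aspartic protease of alveolar type II cells, had 47.9% in lung, 63.0% in skin and 72.0% in brain. Sftpd, surfactant protein D, had 56.3%, 71.5% and 75.8% in the same order.

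Neuronal genes differed between tissues in how much of the promoter was called methylated. Of the 10 brain neuron genes, 9 had a lower called share in brain tissue, with a median of -13.0 points (percentile 0.16). Camk2a, a synaptic kinase, had 20.9% of its promoter called in brain against 70.7% in skin and 71.3% in lung. Grin1, a subunit of the NMDA receptor, had 3.30% against 34.1% and 34.0%, and the synapsin gene Syn1 21.1% against 35.2% and 47.0%. By level, the 5 neuronal promoters with a region in every library had a median of 1.36 points in brain (percentile 19.1, random lists 4.71 points). The level of the other 5 could not be compared in every library. The glial list had a median of 5.63 points by level in brain (percentile 70.8). Within it the myelin gene Mbp had a level of 61.8% in brain, 38.0% in skin and 73.9% in lung. Only 43.5%, 13.3% and 5.75% of its promoter was called there, so these levels rest on unlike parts of it and are hard to compare. Dcn, which codes for the matrix proteoglycan decorin, had 36.3% in skin, 50.1% in lung and 80.9% in brain. The 7 measured endothelial and fibroblast promoters were each higher in brain, with a median of 7.95 points (percentile 94.9, random lists 4.61 points).

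**Figure D1:**
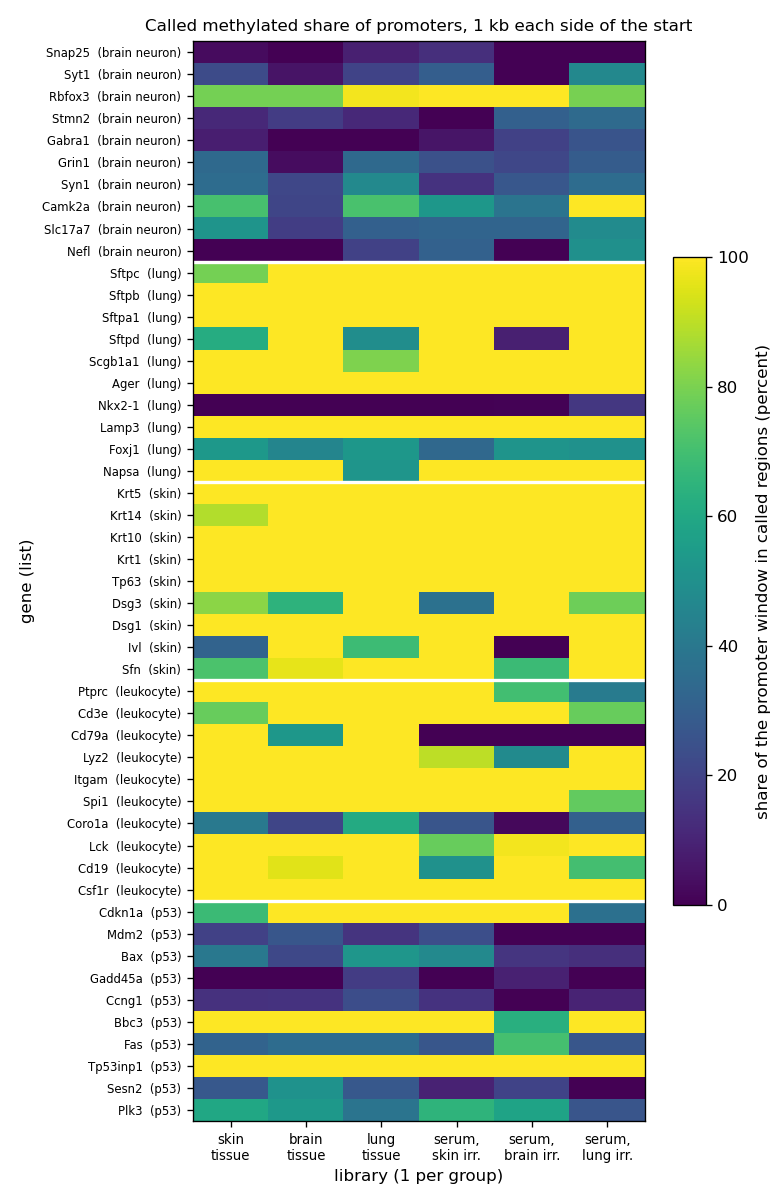
Each cell gives the percent of the 1 kb on both sides of a gene's start that lay in called methylated regions, with genes of 5 lists in rows and the 6 libraries with values in columns. Camk2a and Grin1 were lowest in brain tissue, Napsa in lung tissue, and Cd79a was at 0 in the 3 sera.

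Across 6675 promoters rich in sites, the genes lowest in brain tissue by level were Tob1, Pcdh9, Zfp238, Aatk and Lrrc4. Tob1, an antiproliferative regulator, had 26.1% in brain, 77.4% in skin and 78.8% in lung. The protocadherin gene Pcdh9 had 30.3% against 74.2% and 77.8%, and Zfp238, a transcriptional repressor of neuronal development, 29.1% against 75.2% and 74.5%. The kinase gene Aatk and the synaptic adhesion gene Lrrc4 lay 45.5 and 44.2 points apart from the other tissues, with 28.6% and 34.3% in brain. Cacna1e, a voltage-gated calcium channel, was highest in brain with 77.4% against 37.2% in skin and 33.6% in lung, followed by Ntf3, Efna1, Dcn and Doc2a. Ntf3, which codes for neurotrophin-3, had 76.5% in brain.

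Skin tissue had its lowest promoters relative to the other tissues at Mical1, Tagln2, Tm7sf2, Slc27a4 and Col16a1. Mical1, an actin-oxidizing enzyme, had 31.7% in skin, 78.2% in brain and 80.2% in lung, and the fatty acid transporter gene Slc27a4 38.0%, 79.6% and 77.7%. Lrrc4, Smpd2, Adora1, Mast3 and Tob1 were highest in skin relative to the mean of the others, by 24.9 to 30.2 points. For Lrrc4, Adora1 and Tob1 that mean rests on a low level in brain, and lung tissue had 73.1%, 64.9% and 78.8%. Lung tissue was lowest at Wipf1, Mmp23, Phactr4, Elf1 and Elovl1. Wipf1, a regulator of the actin cytoskeleton in blood cells, had 30.6% in lung, 68.2% in skin and 77.1% in brain, and the ETS factor gene Elf1 43.6%, 68.0% and 85.2%. Tbc1d16, Zfp532, Ech1, Axin2 and Hps4 were highest in lung, for example 75.9% at Tbc1d16 against 42.0% in skin and 30.4% in brain.

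By called share the genes that stood out included C1qa, a complement component, with 31.6% in skin tissue against 100% in both other tissues. Gng3, a G protein subunit of neurons, had 16.4% in brain against 92.5% in skin and 97.7% in lung. S100b, a calcium-binding protein of glia, had 100% in lung, 29.9% in brain and 24.5% in skin. Nr3c1, the glucocorticoid receptor, had 98.6% in lung, 36.0% in brain and 19.2% in skin. Promoters with a called share 30 points or more below both other tissues numbered 614 in skin, 537 in brain and 365 in lung.

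Most regions matched between tissues had similar levels. The lists hold called methylated regions only and matching requires similar borders, so many possible differences could not enter this count. Of the 170953 skin tissue regions, 64471 were matched to brain tissue. The same limit holds for matched regions of the sera. Skin was 0.3 or more above brain in 46 and below it in 120 of 64471 matched regions, with a mean difference of -4.87 points. Skin was above lung in 40 and below it in 62 of 73091, and brain was above lung in 92 and below it in 43 of 61976. The majority direction depended on the matching. In 10 kb bins, skin was above brain in 24 and below it in 8 bins, and brain was above lung in 2 and below it in 42 of 185684.

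Among the sera, the radiation list differed between the libraries in called share. The list was set before the data were examined, but the called share was added afterwards. Organ and dose differed between all these sera, and the beam differed for lung. A difference can therefore not be assigned to organ, dose or beam. Without values for control serum, it can also not be assigned to irradiation. The 10 promoters of the radiation and p53 response list had a median difference in called share of -13.4 points in serum after lung irradiation against the other sera (percentile 0.39). In serum after skin irradiation 6 of 10 promoters were higher (percentile 99.8 for the median), with a mean of 11.2 points (percentile 96.0 for the mean). Cdkn1a, the p53-induced inhibitor of the cell cycle, had 36.7% of its promoter called after lung irradiation and 100% in both other sera. Bax, a promoter of apoptosis, had 13.6% after lung, 15.2% after brain and 46.9% after skin irradiation. The death receptor gene Fas had 70.3% after brain irradiation and 26.7% in both other sera. By level, the 6 measured promoters of this list had a median of 4.11 points after lung irradiation (percentile 93.0), the opposite direction. A low stretch that drops out of the lists lowers the called share and can raise the level of the rest. The opposite directions therefore need not conflict, and the level covers the called part alone.

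Serum after skin irradiation had its lowest promoter levels relative to the other sera at Eogt, Galnt11, Cmtm7, Ndufab1 and Map1b. Eogt, a glycosyltransferase gene, had 27.4% against 85.3% after brain and 85.4% after lung irradiation, and Galnt11, which also codes for a glycosyltransferase, 24.8% against 82.4% and 81.7%. Fam20a, Arhgap22, Psmb1, Tpm1 and Cpeb4 were highest there. Serum after brain irradiation was lowest at Kcng3, Cd302, Tmem104, Hspa12b and Ap5z1, with 24.6% at the potassium channel gene Kcng3 against 78.7% after skin and 81.4% after lung irradiation. Ndst2, Acss1, Ghsr, Tmem54 and Sox7 were highest there. Serum after lung irradiation was lowest at Kazn, Pigh, Ankrd28, Prkcdbp and Ampd2, with 26.1% at Kazn, a gene of desmosome-associated kazrin, a difference of -53.1 points from the mean of the other sera. Cbln4, Nhlrc2, Apobec3b, Lmo1 and Akap2 were highest there, with 77.8% at the cytidine deaminase gene Apobec3b against 37.6% and 33.5%.

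Matched regions differed by 0.3 or more in 0.314% to 0.353% of cases between sera and in 0.140% to 0.257% between tissues, an order that depended on the matching. With 1 bp overlap it turned, to 1.63% to 1.72% between sera and 2.79% to 3.83% between tissues, and in 10 kb bins the ranges overlapped. Under 1 bp overlap a region of the library named first is set against the mean of all regions overlapping it, which can be much longer. The library named first was lower in most such differences: brain tissue was below lung tissue in 4712 and above it in 204. The mean difference there was 0.835 points in the other direction. The 1 bp values are therefore not a rate of differences between sera or between tissues. Serum after skin irradiation was 0.3 or more above serum after brain irradiation in 69 and below it in 108 of 50121 regions. It was above serum after lung irradiation in 66 and below it in 94 of 50993. Serum after brain irradiation was above serum after lung irradiation in 79 and below it in 92 of 51660. That direction turned in 10 kb bins, with 7 above and 2 below. The SD of the differences was 6.56 to 6.80 points between sera and 5.58 to 6.28 points between tissues, and with 1 bp overlap 8.97 to 9.11 and 9.47 to 11.5 points.

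Compared with the 3 tissues, the 3 sera had less of the promoters of leukocyte genes called methylated, within a lower called share of promoters in general. The mean called share over all protein-coding promoters was 48.1% to 50.2% in the sera and 53.7% to 55.8% in the tissues. Of the 10 leukocyte promoters, 7 had a lower called share in the sera, 3 were equal and 0 were higher, with a median of -14.5 points (percentile 1.17, random lists -2.65 points). The erythroid list had a median of -22.0 points with 4 of 5 genes lower (percentile 8.43). The olfactory receptor genes, a list added after the data were seen, had -9.56 points with 693 of 1117 lower (percentile 0, random lists 0 points). A low percentile in this comparison was therefore not particular to leukocyte genes. A promoter without calls in serum may also lack reads. Cd79a, a chain of the B cell receptor and named after the values were seen, had 0% in each serum, 100% in skin and lung tissue and 52.8% in brain tissue. Coro1a, an actin-binding protein of leukocytes, had 26.5%, 2.15% and 30.8% in serum after skin, brain and lung irradiation, against 40.5%, 20.9% and 61.3% in those tissues. Ptprc, the common leukocyte antigen, had 69.7% after brain and 41.8% after lung irradiation and 100% in the other libraries. By level, the 9 leukocyte promoters with a region in every library had a median of 1.32 points and a mean of -1.85 points, which differ in sign. Both lay below the random lists, at 3.28 points for the median (percentile 14.96) and 2.84 points for the mean (percentile 3.23). Neuronal promoters were higher in the sera in 9 of 10 genes by called share, with a median of 7.84 points (percentile 99.1). This rested on brain tissue: against skin and lung tissue alone 5 of 10 genes were higher, with a median of 1.32 points, a comparison added after the values were seen. By pairs from the same irradiation, the mean called share of leukocyte promoters was lower in serum in 3 of 3 pairs (mean -19.7 points, SD 6.05, exact sign-flip permutation p = 0.25). It was higher for neuronal promoters in 2 of 3 pairs and lower for erythroid promoters in 2 of 3 (exact sign-flip permutation p = 0.5 each).

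Whether each serum resembled the organ that was irradiated was asked by pairing sera and tissues. Serum after skin irradiation had r = 0.602 with skin, 0.544 with brain and 0.665 with lung tissue. Serum after brain irradiation had 0.613 with skin, 0.574 with brain and 0.679 with lung tissue, and serum after lung irradiation 0.629, 0.577 and 0.688. These correlations are across 44651 to 52422 regions, which are not independent replicates. Each serum had its highest correlation with lung tissue and its lowest with brain tissue. Across matched regions lung was also the nearest tissue to skin (r = 0.762) and to brain (0.710), against 0.694 between skin and brain. In 10 kb bins brain tissue was nearer to skin (0.511) than to lung (0.497). The mean r of the matched pairs lay 0.00210 above the mean of all pairs (one-sided exact permutation p = 0.333, 6 pairings). In 10 kb bins the value was 0.00490 and the matched pairing was the highest of the 6 (exact permutation p = 0.167, the smallest that the design allows), also with any 1 of 21 chromosomes left out. The matched pairing was also the highest in regions longer than the median (0.00452) and by Spearman's rho (0.00286). It was not the highest with 1 bp overlap (0.000261), on autosomes only (0.00197) or by the mean absolute difference (0.00131), each with exact permutation p = 0.333. In simulated sera the statistic in bins averaged 0.000138 (SD 0.000764) with none of the signal from the own organ. It averaged 0.00527 with 2% of it, under noise that was independent between sera. Those sera were built from the same tissue libraries they were compared with, so the observed value does not give a share of organ DNA. A p of 0.167 does not separate the pairing from chance.

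**Figure D2:**
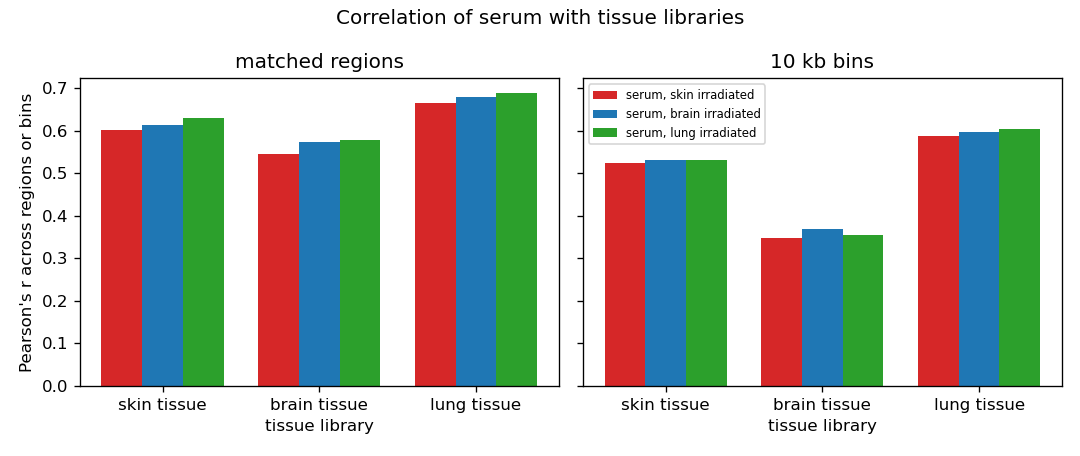
Bars give Pearson's r between each serum and each tissue library, across matched regions on the left and 10 kb bins on the right, with bar color for the irradiated organ of the serum donor. The 3 sera had r of 0.665 to 0.688 with lung tissue and 0.544 to 0.577 with brain tissue across matched regions.

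Marker regions of the tissues could not show whether serum carried DNA of the irradiated organ. The planned matching found 11 regions lower in skin, 7 lower in brain and 5 lower in lung than in both other tissues, and 0 to 2 of them per tissue and serum had a serum value. With 1 bp overlap there were 3409, 3400 and 1430 markers. Their tissue levels were 33.8%, 31.9% and 32.2%, against 76.6%, 74.9% and 75.1% in the other tissues. Serum after skin, brain and lung irradiation had 76.3%, 77.7% and 78.0% at the skin markers, 77.8%, 79.3% and 79.7% at the brain markers, and 74.1% to 75.9% at the lung markers. The pairing statistic, positive where matched sera lie nearer to their tissue, was -0.0954 points (exact permutation p = 1, 6 pairings). Under this rule a serum value is that of the whole overlapping region, which can be much longer than the marker, so it need not reflect the marker itself. The same holds for the values of the other tissues by which the markers were chosen. Many markers may therefore be short low regions set against longer ones and not differences between tissues. In 10 kb bins there were 1, 20 and 2 lower in skin, brain and lung. Markers higher in 1 tissue numbered 8, 30 and 4, so the statistic is no evidence for or against DNA of the irradiated organ in serum.

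At promoters with a low called share in 1 tissue, sera lay between that tissue and the other 2. These promoters were chosen as extremes of 1 tissue library, so intermediate values are also likely in a library unrelated to that tissue. Sera after irradiation of the other organs also lay between, so these values are no evidence of that tissue's DNA in serum. At the 614 skin marker promoters, skin tissue had 38.4% called and the other tissues 88.9%, and sera after skin, brain and lung irradiation had 60.1%, 63.7% and 66.1%. At the 537 brain marker promoters, sera had 53.5% to 55.1%, and at the 365 lung marker promoters 55.3%, 58.1% and 61.3%. Among these promoters, Napsa had 100% called in the 3 sera, and Camk2a 53.1%, 38.4% and 100% after skin, brain and lung irradiation. The pairing statistic at marker promoters was -0.104 points (exact permutation p = 0.667, 6 pairings). At the 148986 stretches uncalled in 1 tissue it was 0.153 points (exact permutation p = 0.667), and 0.118 to 0.323 points with other minimum lengths or on autosomes.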

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

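No paired analysis was possible because each group had 1 library, for comparisons between irradiations or organs. Serum and tissue were also compared over the 3 pairs from the same irradiation, where the smallest p is 0.25. A change of a mean level was judged against the SD over autosomes, since there were no replicates, a change of a count against 1.5 times, and a change of a pairing statistic by its sign alone. The promoter and stretch results, the marker statistic with 1 bp overlap and their alternatives were chosen after seeing the data. Depth is unknown and limits every level. The comparison with control serum gave no value under any setting, coverage minimums could not be applied, and long regions left too few markers for a pairing statistic. Of 147 alternative values, 85 stayed within these limits. The unweighted mean level was 70.2%, 74.3% and 71.5% in skin, brain and lung tissue and 75.4%, 76.2% and 76.3% in serum after skin, brain and lung irradiation. Medians were 73.3% and 74.7% in skin and lung tissue and 78.2%, 79.6% and 79.7% in the sera. Regions longer than the median had 75.6%, 80.6% and 77.3% in the tissues and 79.7%, 81.2% and 81.4% in the sera. Counts of different regions are given for skin with brain, skin with lung and brain with lung tissue, then for serum after skin with brain, skin with lung and brain with lung irradiation. They were 6177, 4664, 4916, 2141, 2028 and 1922 with 1 bp overlap, 32, 4, 44, 14, 14 and 9 in 10 kb bins, and 2, 2, 1, 2, 2 and 1 in regions longer than the median. The counts with 1 bp overlap set a region against regions that can be much longer, so they are not a rate of differences. At a threshold of 0.2 they were 1072, 655, 803, 954, 913 and 864, and at 0.4 they were 24, 12, 19, 29, 26 and 25. Tissue marker regions numbered 23 as planned, 1 in regions longer than the median, 8239 with 1 bp overlap, 161 at a threshold of 0.2, 3 at 0.4, and 10 for markers higher in 1 tissue. By the mean absolute difference, 1 serum was nearest to lung tissue and 0 were farthest from brain tissue. Marker promoters numbered 1516, and 2685 at 20 points and 871 at 40 points. Stretches uncalled in 1 tissue numbered 148986, and 231768, 61809 and 15220 with minimums of 200, 1000 and 2000 bp. The resemblance statistic stayed above 0 under the settings run, from 0.000261 with 1 bp overlap to 0.00490 in 10 kb bins. The statistic at marker regions changed sign to 0.0190 points at a threshold of 0.4 (exact permutation p = 0.5), and moved the other way to -2.15 points in 10 kb bins and -0.558 points for markers higher in 1 tissue. The statistic at marker promoters was -0.763 points with 2000 bp on each side. It changed sign to 0.152 points on autosomes only (exact permutation p = 0.5) and reached 0.321 points leaving out 1 chromosome (exact permutation p = 0.333). For each of these the cause was not tested.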

Other observations

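The tests of explanations below were chosen after the patterns were seen, and the expected outcomes for region matching and for blood cells were written down after the values were known. Several gene lists showed further differences between libraries. Muscle promoters Acta1 and Des, which code for skeletal actin and desmin, had 100% of the promoter called in brain tissue and 39.3% and 43.2% in skin tissue. The other muscle promoters were lower in brain for 1 gene and equal for 2, and the list's median was 0 (percentile 43.3). Of the 10 imprinted promoters, 6 had a lower called share in serum after brain irradiation, with a median of -20.3 points (percentile 1.35). The mean was -15.0 points (percentile 9.95). By level, 5 of 9 were higher in that serum, with a median of 2.46 points (percentile 70.2). By called share, Grb10 had 46.2% in that serum and 100% in the other 5 libraries, and Nnat 46.3% against 75.6% and 74.3% in the other sera. Snrpn had 16.8% in serum after skin irradiation and 100% in the 3 tissues. Erythroid promoters were higher in serum after lung irradiation in 3 of 5 genes, with a median of 32.9 points (percentile 98.3).

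Germline genes had means of 100% called in the 3 tissues and 94.2% to 100% in the sera. Housekeeping promoters had means of 5.59% to 12.7%. In the liver list, Alb, the gene of serum albumin, had 47.8% called in serum after brain irradiation and 100% in the other 5 libraries. DNA repair promoters had a mean called share of 12.6% in serum after skin irradiation, and 25.9% and 25.4% after brain and lung irradiation (percentile 3.52 for the median after skin irradiation). Among the DNA methylation enzymes, Dnmt3b had 96.1% in serum after skin irradiation and 29.5% to 34.4% in the other libraries.

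Each serum correlated best with lung tissue. Matching of separately called regions is not enough to account for this, since 3 of 3 sera also had their highest correlation with lung tissue in fixed bins. The next test asked whether the spread of single differences, in place of a correlation, gives another order. By the mean absolute difference after removing the mean difference, 3 of 3 sera were nearest to lung tissue. Without that removal 1 serum was nearest to lung tissue and the others to brain tissue, whose mean level is close to that of the sera. A correlation also leaves out the mean difference and falls as the spread grows, so the result after removal was likely in advance. It cannot decide whether the pattern comes from the measure. Blood cells within the lung tissue stay open. Leukocyte promoters had a called share 6.80 points higher in lung tissue than in the other 2 tissues, with a standard error over 10 genes of 3.61 points. Of these genes 4 were higher and 6 equal. The error is a spread over genes of 1 library per tissue and not between animals, so these values do not decide the question. By level the direction was the other: 8 of 9 leukocyte promoters were lower in lung tissue, with a median of -3.53 points against -0.707 points in random lists (percentile 5.98). No other biological explanation was tested.

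Less of the X chromosome was called in serum than in tissue. Serum lists covered 48.1%, 51.4% and 54.0% of the tissue's called length on X for skin, brain and lung, and 88.6% to 90.6% on autosomes. A low density of sites with data may account for part of this. In 114 autosomal windows of 1 Mb with the site density of X, serum covered 67.3% on average of the tissue's called length, between the values of X and of all autosomes. The rest stays open, and no biological explanation was tested.

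Promoters of olfactory receptor genes were often uncalled in 1 library. Of the olfactory promoters that could enter the count, 8.94% were lower in skin tissue and 6.54% in lung tissue, against 4.56% and 2.69% of other promoters. Brain tissue showed no excess, with 4.09% against 4.32%, and the 3 sera had ratios of 1.72 to 1.88. Few sites with data per promoter may be a source: at matched site density the olfactory count was 0.927 times that of other promoters, the median of 6 libraries. Brain tissue lay apart with 0.486 times, for which the cause was not tested, and the other 5 libraries had 0.872 to 1.06 times. Reads shared between these similar genes were not examined, and no biological explanation was tested.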
